A study of Homo sapiens with 6 samples.

How the data were processed

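Gene expression was measured on 6 Affymetrix whole-transcript arrays of human cells, 3 from undifferentiated induced pluripotent stem (iPS) cells and 3 from cells sorted for a PAX7-Venus reporter after 3 weeks of myogenic differentiation. Each array was assigned to its group and replicate number from its title. The titles call the arrays of each group biological replicates 1 to 3, but do not say whether they came from separate cultures, clones or sorts. The p-values therefore measure the spread between these arrays, some of which may be technical. The 3 undifferentiated arrays are marked in their titles as re-analysed and the 3 Venus+ arrays are not, so the origin of the arrays and the group cannot be told apart.

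The values are log2 RMA signals as deposited by the authors, 1 per probe set and array. RMA subtracts background, forces the arrays to a common distribution and summarises the probes of a probe set. Per the submitters' processing notes, RMA was run in R 2.12.1. The probe set annotation, the RMA settings and a genome build are not given in the sources used here, so no coordinates are printed. Per the labels' protocols, differentiated cells were purified by fluorescence-activated sorting with gates set on undifferentiated cultures, and total RNA was amplified in 2 cycles before labelling with biotin. Such amplification can shift the relative signal of transcripts, and a common distribution on every array hides any change in the total amount of RNA per cell.

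The table holds 53617 probe sets. A platform annotation paired 16098 of them with 1 gene symbol and none with several, and 37519 stayed unnamed here. All 16098 named probe sets were matched through their gene identifiers to a RefSeq gene table of the GRCh38.p14 assembly, used for symbols and gene classes only, and 0 symbols changed. The named probe sets stand for 14884 genes, 14105 of them with 1 probe set and 779 with several. A gene was represented by its probe set with the highest mean over all 6 arrays, a choice blind to group. No filter on dim probe sets was applied. A gene with no named probe set was not analysed here. This affects the gene lists unevenly, since 12 of 37 sarcomere genes, 14 of 32 matrix genes, 3 of 18 dystrophin complex genes and 27 of 39 HOX genes were measured. MYH3, which had been chosen for reporting, was among those not analysed here.

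All 53617 probe sets entered 1 linear model per probe set in limma 3.58.1 under R 4.3.3, with the group as the sole factor and no block, followed by empirical Bayes moderation (lmFit and eBayes). Differences are Venus+ minus undifferentiated on the log2 scale, with the standard error (SE) from the moderated fit and two-sided p-values. P-values were adjusted by the Benjamini-Hochberg method over the 14884 genes. A gene was called where its adjusted p was under 0.05 and its log2 difference was at least 1 in size, a 2-fold difference. The number of arrays, 3 per group, limits the precision. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes were tested in the shared model alone.

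There were 26 gene lists, fixed before the data were examined. Each list was tested with limma's camera, which asks whether its members rank higher or lower than the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists. Counts of called members were made over all genes and again adjusted over the list alone. The lists covered pluripotency, epithelial genes, myogenic progenitors, myogenic commitment, sarcomere, synapse and calcium coupling, the dystrophin complex, extracellular matrix, cell cycle, CDK inhibitors, the Notch, WNT, BMP and TGF-beta, and FGF and IGF pathways, HOX genes and imprinted genes. Others held markers of neural progenitors, neurons, neural crest and glia, skeletogenic cells, fibroblasts, endothelium, heart and smooth muscle, endoderm, and presomitic mesoderm, and immediate-early and stress genes that sorting can raise. A separate list of 21 housekeeping genes, 10 of them measured, served for centring.

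The genes named in the report were also chosen by a rule set before the data were examined. It names PAX7, 11 marker genes, the 8 called genes with the largest difference in each direction whose arrays do not overlap between the groups, and from each list the 3 called members with the largest difference in size, or the 2 largest differences where none was called. A further called member was added where it went the other way. XIST, genes of the Y chromosome, unnamed probe sets and LOC symbols were left out. Other genes named as examples were chosen after their values were seen.

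The steps were tested on simulated data built on this comparison and its 14884 genes, with 200 genes changed by known amounts and the 20 measured Notch genes shifted. At a log2 change of 1.5, 91 of 100 genes were recovered, at 3 all 100 of 100, and 0 of the 14664 genes outside both sets were called. The shifted Notch list was called, and 0 of the 25 others. The simulated genes varied independently of one another, whereas the estimated correlation of real lists reached 0.60 (extracellular matrix). The simulation therefore cannot show how often camera calls a list falsely on these data. It also gave both groups the same spread and changed far fewer genes than the 7240 whose adjusted p was under 0.05 in the real data. Its counts of recovered and falsely called genes may therefore not hold for these data.

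Alternatives were other choices of probe set, centring on the housekeeping genes, a second quantile normalisation, cyclic loess, a trended and robust variance, other thresholds, limma's treat, the replicate number as a block, each array left out in turn, camera with an estimated correlation, and fry. A filter on the level of olfactory receptor probe sets had been planned, but only 1 named probe set of that family was present. A filter at the median of all probe sets was run in its place and was chosen after the data were seen, as were a count over protein-coding genes and housekeeping centring with HPRT1 left out. Leaving out probe sets by name suffix, and comparing 3' with 5' probe sets of actin and GAPDH as a sign of RNA quality, had been planned for another array type and were not run, because the probe set names here carry no such marks.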

Results

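The series measured gene expression in human iPS cells before and after myogenic differentiation. The 3 undifferentiated samples are of NCRM-1, an established human iPS line grown in a feeder-free medium. The other 3 samples are cells that had been through 3 weeks of serum-free myogenic differentiation and were then sorted for Venus, a yellow fluorescent protein reporting PAX7, a transcription factor of muscle progenitor and satellite cells. The labels do not say from which parent line the reporter cells were made. The comparison asks which genes differ between the sorted PAX7-Venus+ cells and pluripotent cells. Every array gave a log2 signal for 53617 probe sets, with medians of 3.86 to 3.99 and values from 1.54 to 13.78.

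The 2 groups were well separated. Pearson correlations over all probe sets were 0.992 to 0.993 within the undifferentiated arrays, 0.981 to 0.986 within the Venus+ arrays and 0.907 to 0.916 between the groups. The first principal component, with 83.6% of the variance, parted the groups. The second held 6.73% and parted the Venus+ arrays, with replicate 1 at 52.8, replicate 2 at -18.3 and replicate 3 at -36.2. The median SD of a probe set was 0.108 in the undifferentiated group and 0.160 in the Venus+ group.

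PAX7 itself, the gene behind the sort, rose from a signal of 4.47 ± 0.28 (SD, n = 3) in undifferentiated cells to 7.36 ± 0.27 (SD, n = 3) in Venus+ cells. This is a log2 difference of 2.89 (SE 0.19), or 7.39-fold, with an adjusted p of 1.7e-05 in limma. The largest rises among called genes were those of LUM (lumican) and KLHL41, which encodes a protein of the muscle sarcomere, at 349-fold and 295-fold. LUM went from 2.74 ± 0.13 to 11.19 ± 0.25 and KLHL41 from 2.63 ± 0.08 to 10.83 ± 0.20 (SD, n = 3 each). They were followed by the matrix genes DCN (78.0-fold) and MGP (77.6-fold), the long non-coding RNA LINC02381 (60.8-fold), the myogenic factors MYF5 (55.2-fold) and MYF6 (50.4-fold), and RBM24 (52.5-fold), which encodes an RNA-binding protein of muscle. The adjusted p-values of these 8 genes in limma lay between 1.5e-07 and 1.1e-05. Their undifferentiated signals of 2.63 to 3.66 were below the array median of 3.93 and not shown to be above background, so the exact folds and their order are uncertain.

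The largest falls were those of the microRNA gene MIR302C (177-fold lower) and of 3 genes typical of pluripotent cells, ESRG (176-fold), L1TD1 (140-fold) and LIN28A (119-fold). LIN28A, which encodes an RNA-binding protein that blocks let-7 maturation, went from 11.51 ± 0.06 to 4.61 ± 0.52 (SD, n = 3 each). D21S2088E fell 104-fold, MIR302D 70.2-fold, MIR302B 66.5-fold, and ESRP1, which encodes a splicing regulator of epithelial cells, 66.3-fold. The Venus+ signals of 6 of these 8 genes, all but LIN28A and MIR302B, were below 3.93 and not shown to be above background, so here too the exact folds and their order are uncertain. The probe sets of microRNA genes read the annotated locus and do not measure the mature microRNA.

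**Figure D1:**
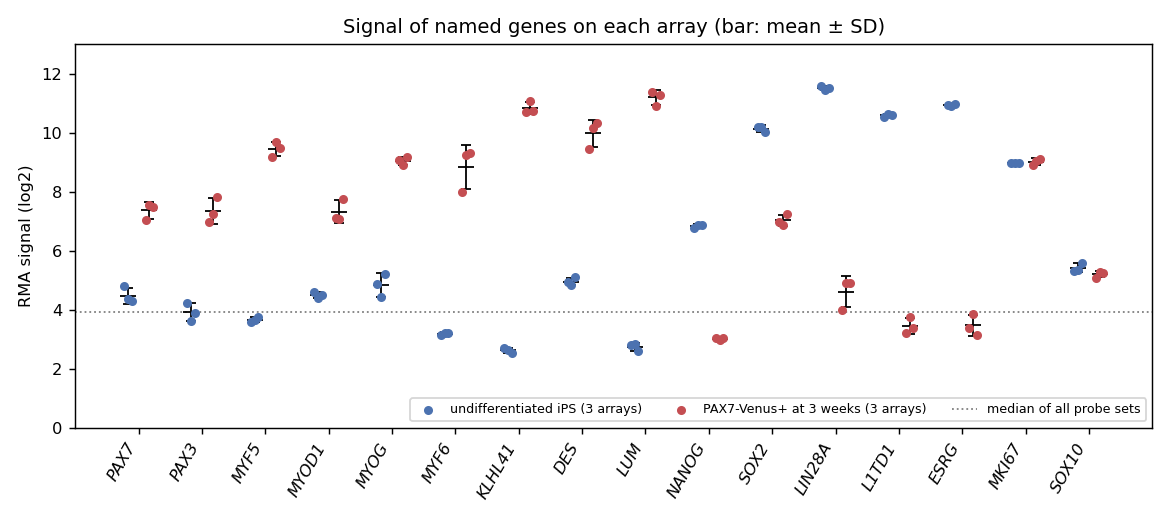
Log2 RMA signal (y axis) of 16 named genes (x axis) on each of the 3 undifferentiated iPS arrays (blue) and the 3 PAX7-Venus+ arrays (red), with bars for mean ± SD and a dotted line at 3.93, the median of all probe sets and arrays. MYF5 lies at 3.66 and 9.45 in the respective groups and NANOG at 6.84 and 3.02, while MKI67 lies at 8.97 and 9.01.

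In all, 2910 of the 14884 genes were called, 1045 higher and 1865 lower in Venus+ cells, so 35.9% of the calls were rises. Of these, 318 rose and 483 fell by at least 4-fold, and 59 rose and 37 fell by at least 16-fold. By class, 918 protein-coding genes rose and 1756 fell, 46 long non-coding RNA genes rose and 59 fell, and 52 microRNA genes rose and 25 fell. In each of the 2910 called genes the 3 arrays of one group all lay above the 3 of the other. Such separation was found in 59.4% of all genes, against 10% by chance. The split depends on the scale, because centring the arrays on 10 housekeeping genes moved the median gene by 0.40 and gave 1936 higher and 1080 lower genes (64.2% rises). HPRT1 carried part of that shift, with a difference of -1.65 against a median of -0.26 over the 10 genes. With HPRT1 left out, an alternative chosen after the data were seen, the shift was 0.26 and 1540 genes were higher and 1312 lower (54.0% rises). The split also depends on the use of named probe sets, since 3686 were higher and 3938 lower when every probe set was counted on its own, and among those without a gene name 2587 were higher and 1997 lower.

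For the gene groups that follow, counts of called members adjusted over the list alone were identical to those over all genes in each of the 26 lists. With the preset correlation 13 of the 26 lists were called, and 3 held with an estimated correlation, those of pluripotency, epithelial and myogenic commitment genes. The estimated setting also cuts the degrees of freedom of the test to the residual 4, so its higher p-values do not reflect correlation alone. The median differed in sign from the mean or the test in 3 lists, the dystrophin complex, neural progenitor and endothelial lists.

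Of 22 measured genes of the pluripotent state 16 fell and 0 rose, with a median log2 difference of -2.98 (camera in limma, adjusted p = 4.6e-08, and adjusted p = 0.0467 with an estimated correlation). DPPA2 (-0.24), GDF3 (-0.19), LEFTY1 (-0.15), NODAL (-0.23), UTF1 (-0.15) and LEFTY2, at 0.57 (SE 0.12), were not called. Their undifferentiated signals were only 3.95 (NODAL) to 5.42 (LEFTY2), against 5.95 (VRTN) to 11.51 (LIN28A) for the called members. They had less room to fall, so the lack of a call does not show that their expression was kept. NANOG, a core pluripotency factor, fell by 3.82 (SE 0.08) and SOX2 fell by 3.10 (SE 0.12), from 10.13 ± 0.11 to 7.03 ± 0.19 (SD, n = 3 each). POU5F1 (OCT4) fell by 1.17 (SE 0.20, adjusted p = 0.0019 in limma), from 6.28 to 5.11. POU5F1 has pseudogenes of near-identical sequence, whose transcripts its probes can also read. Its difference was -0.96 without Venus+ replicate 3 and -0.77 with housekeeping centring, both under the 2-fold minimum, and treat did not call it.

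Of 16 measured epithelial genes 13 fell and 0 rose, with a median of -2.45 (camera in limma, adjusted p = 3.3e-08, and adjusted p = 0.0399 with an estimated correlation). Beside ESRP1 the largest falls were those of the tight junction genes OCLN and CLDN7, which encode occludin and claudin-7, by 4.39 (SE 0.17) and 4.19 (SE 0.09). KRT8, CLDN3 and CRB3 were not called, at -0.38, -0.24 and -0.21.

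Among myogenic progenitor genes 17 of 31 measured members rose and 2 fell, with a median of 1.26. The rises were led by MYF5, EYA4 (5.30, SE 0.13) and EYA1 (5.17, SE 0.23). PAX3, the paralog of PAX7 in the dermomyotome, rose by 3.43 (SE 0.24), from 3.91 ± 0.30 to 7.34 ± 0.44 (SD, n = 3 each). SDC4, which encodes a heparan sulfate proteoglycan also found on satellite cells, fell by 1.95 (SE 0.11), from a high undifferentiated level of 8.89. Camera gave the list an adjusted p = 2.5e-07 in limma, and an adjusted p = 0.0701 with an estimated correlation.

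Of the genes of myogenic commitment, 14 of 17 measured members rose and 0 fell, with a median of 2.46. MYF5 rose from 3.66 ± 0.10 to 9.45 ± 0.25, MYOG from 4.83 ± 0.40 to 9.05 ± 0.14 and MYOD1 from 4.49 ± 0.10 to 7.31 ± 0.39 (SD, n = 3 each). All 3 encode basic helix-loop-helix factors of the muscle lineage, and MYOG (log2 difference 4.21, SE 0.20) marks differentiating myoblasts. The list was called in camera with an adjusted p of 3.5e-11 in limma and an adjusted p = 0.0399 with an estimated correlation. MYF5 is counted in this list and in that of the progenitors.

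Of the sarcomere genes 12 of 37 were measured, and 9 of these rose with 0 falling (median 1.12, camera in limma, adjusted p = 1.1e-05). The adjusted p = 0.194 with an estimated correlation. DES, which encodes desmin, rose by 5.02 (SE 0.22), NEB (nebulin) by 4.92 (SE 0.10) and TTN (titin) by 3.36 (SE 0.30). A second TTN probe set gave 0.00 (SE 0.09), so the titin value rests on 1 of 2 probe sets, while a second DES probe set gave 3.88. The mean signal of the list was 7.03 in Venus+ replicate 1 against 6.64 and 6.68 in replicates 2 and 3, and without replicate 1 the count of rises was 6, with TPM1, LDB3 and MYOZ2 below 2-fold.

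The synapse and calcium coupling list also held muscle energy genes. Of its genes 10 of 23 were measured, of which 5 rose and 0 fell (median 0.85). Camera in limma gave an adjusted p = 0.0068, and an adjusted p = 0.133 with an estimated correlation. CHRNA1, CHRNB1, CHRND, CHRNG, CHRNE and MUSK were not analysed here. RAPSN, which rose by 2.45 (SE 0.14), was therefore the only synapse gene measured. The energy genes PGAM2 (-0.34) and MB (0.35) were not called. The rises were led by SRL (4.55, SE 0.17) and CASQ2 (3.78, SE 0.38), which encode calcium-binding proteins of the sarcoplasmic reticulum, and by STAC3 (4.05, SE 0.14), a component of excitation-contraction coupling. Of 3 measured dystrophin complex genes, DMD (dystrophin) rose by 1.31 (SE 0.15), while UTRN (-0.30) and SSPN (-0.14) were not called. The median of that list was -0.14, or 0.26 with housekeeping centring, and its adjusted p was 0.727 in camera.

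**Figure D2:**
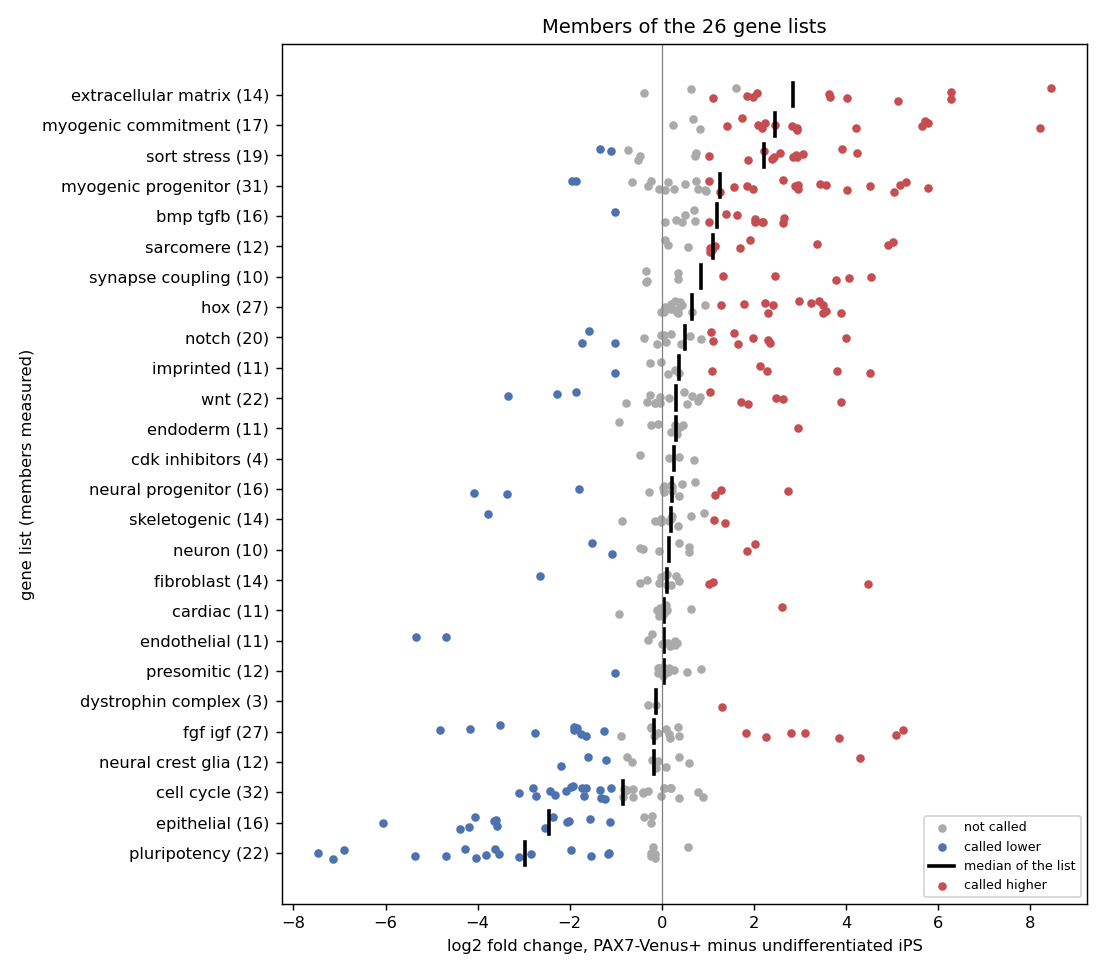
Log2 difference, PAX7-Venus+ minus undifferentiated iPS (x axis), of each measured member of the 26 gene lists (y axis, with the number measured), in red where called higher, blue where called lower and grey where not called. Black bars mark list medians, from 2.85 for extracellular matrix to -2.98 for pluripotency.

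Extracellular matrix genes had the highest median of the 26 lists, 2.85, with 11 of 14 measured members higher and 0 lower (camera in limma, adjusted p = 9.3e-08). The adjusted p = 0.270 with an estimated correlation. LUM and DCN encode small leucine-rich proteoglycans that bind collagen, and MGP encodes an inhibitor of calcification. Their log2 differences were 8.45 (SE 0.15), 6.29 (SE 0.12) and 6.28 (SE 0.24). The collagens and laminins of the list were not analysed here. The mean signal of the list was 9.69 in Venus+ replicate 1, against 8.83 and 8.95 in replicates 2 and 3 and 5.80 to 5.88 in the undifferentiated arrays.

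Cell cycle genes fell in part. Of 32 measured members 15 fell and 0 rose, with a median of -0.83 (camera in limma, adjusted p = 2.1e-05, and adjusted p = 0.454 with an estimated correlation). The largest falls were in genes of replication licensing, in CDC6, which fell by 3.09 (SE 0.12), and in the MCM helicase genes, where MCM3 fell by 2.79 (SE 0.09) and MCM5 fell by 2.73 (SE 0.14). MKI67, a proliferation marker, was at 8.97 ± 0.01 and 9.01 ± 0.11 (SD, n = 3 each), a difference of 0.04 (SE 0.09, adjusted p = 0.737 in limma) that became 0.45 with housekeeping centring. With that centring 11 members of the list were lower and 2, CDK1 and KIF20A, were higher. The list mean was 7.41 in Venus+ replicate 1 against 7.63 and 7.75 in replicates 2 and 3, and without replicate 1 CDK1 was called higher, at 1.08.

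Of the CDK inhibitor and pocket protein genes 4 of 10 were measured and 0 were called in limma, while 2 passed the adjusted p with no fold minimum (median 0.27, camera adjusted p = 0.325). RB1, the retinoblastoma gene, differed by 0.70 (SE 0.09), which passes the p threshold (adjusted p = 6.2e-04 in limma) but not the 2-fold minimum. It reached 1.10 with housekeeping centring, and 0.96 when HPRT1 was left out of the centring. RBL1 differed by -0.47 (SE 0.20, adjusted p = 0.0839 in limma). The only CDK inhibitor gene measured was CDKN2A, at 0.16 (adjusted p = 0.397 in limma). Its signals of 3.27 in undifferentiated and 3.44 in Venus+ cells were below the array median of 3.93. CDKN1A, CDKN1B, CDKN1C, CDKN2B, CDKN2C and CDKN2D were not analysed here, so the list says little on CDK inhibitors.

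**Figure D3:**
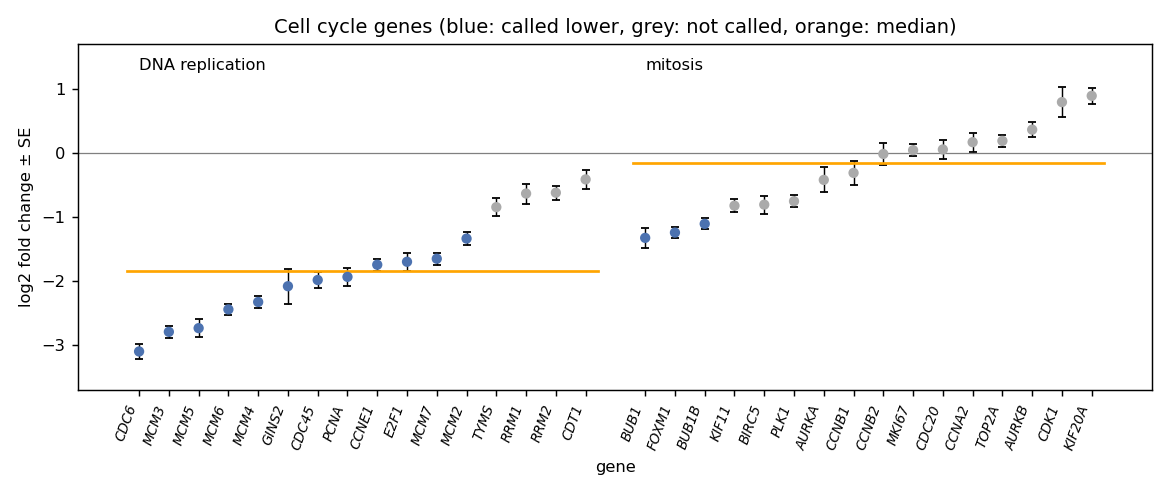
Log2 difference ± SE, PAX7-Venus+ minus undifferentiated iPS (y axis), of 32 cell cycle genes (x axis), arranged as DNA replication and mitosis genes, an arrangement chosen after the values were seen. Called falls are blue, other genes grey, and orange lines mark medians of -1.84 for replication and -0.16 for mitosis, the latter 0.24 with housekeeping centring.

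Notch pathway genes moved in both directions, with 8 of 20 measured members higher and 3 lower (median 0.51, camera in limma, adjusted p = 0.010, and adjusted p = 0.201 with an estimated correlation). With housekeeping centring the adjusted p was 0.127. HEY1, a target of Notch signalling, rose by 4.01 (SE 0.23) and the ligand gene DLL1 by 2.34 (SE 0.13), whereas the related target HEY2 fell by 1.73 (SE 0.10). The coactivator gene MAML2 rose by 2.32 (SE 0.10) in its brighter probe set and differed by 0.35 in the other.

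Of the WNT pathway genes 22 of 32 were measured, of which 6 rose and 3 fell (median 0.32, camera in limma, adjusted p = 0.124). The WNT ligand genes of the list, TCF7, TCF7L1 and TCF7L2 were not analysed here. Among measured members that encode secreted WNT antagonists, FRZB rose by 3.89 (SE 0.14) and DKK2 by 1.88 (SE 0.15), SFRP2 fell by 3.35 (SE 0.17) and SFRP1 fell by 2.28 (SE 0.22), and DKK1 (0.55), DKK3 (-0.33) and SFRP4 (0.78) were not called. LEF1, a transcription factor of the pathway, rose by 2.63 (SE 0.18). The target gene AXIN2 (-0.03) was not called, nor were NKD1 (-0.04), NKD2 (0.15), RNF43 (-0.15), ZNRF3 (-0.14) and LGR5 (0.48).

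Of the BMP, TGF-beta and activin genes 16 of 30 were measured, of which 9 rose and 1 fell (median 1.21, camera in limma, adjusted p = 3.5e-05, and adjusted p = 0.0789 with an estimated correlation). BMP5 rose by 2.64 (SE 0.38), BMP4 by 2.63 (SE 0.17) and MSTN, which encodes the muscle growth inhibitor myostatin, by 2.21 (SE 0.23). Of the measured members that encode antagonists of these pathways, NOG, GREM1, FST and SMAD6 rose by 2.02, 1.40, 2.18 and 2.03, and CHRD (0.30), BAMBI (0.50) and SMAD7 (0.70) were not called. The ligand genes TGFB1, TGFB2, TGFB3, INHBA and INHBB were not analysed here. GDF11, the paralog of MSTN, fell by 1.03 (SE 0.15), and it was not called when any of 3 single arrays was left out or with housekeeping centring (-0.63), cyclic loess (-0.99) or treat.

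FGF and IGF genes split, with 7 of 27 measured members higher and 10 lower (median -0.16, or 0.24 with housekeeping centring, camera in limma, adjusted p = 0.628). IGFBP5, which encodes an IGF-binding protein, rose by 5.24 (SE 0.22) and the ligand gene FGF9 by 5.08 (SE 0.23). ETV4, which encodes an ETS factor induced by FGF signalling, fell by 4.82 (SE 0.14).

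HOX genes, the homeobox genes that mark position along the body axis, had signals of 2.81 to 5.47 in undifferentiated cells. Of 27 measured members 12 rose and 0 fell in Venus+ cells (median 0.66, camera in limma, adjusted p = 6.2e-08, and adjusted p = 0.0789 with an estimated correlation). HOXC4 rose from 4.29 ± 0.13 to 8.17 ± 0.16 (SD, n = 3 each), by 3.88 (SE 0.12). HOXB9 and HOXB2 rose by 3.58 (SE 0.19) and 3.51 (SE 0.17).

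**Figure D4:**
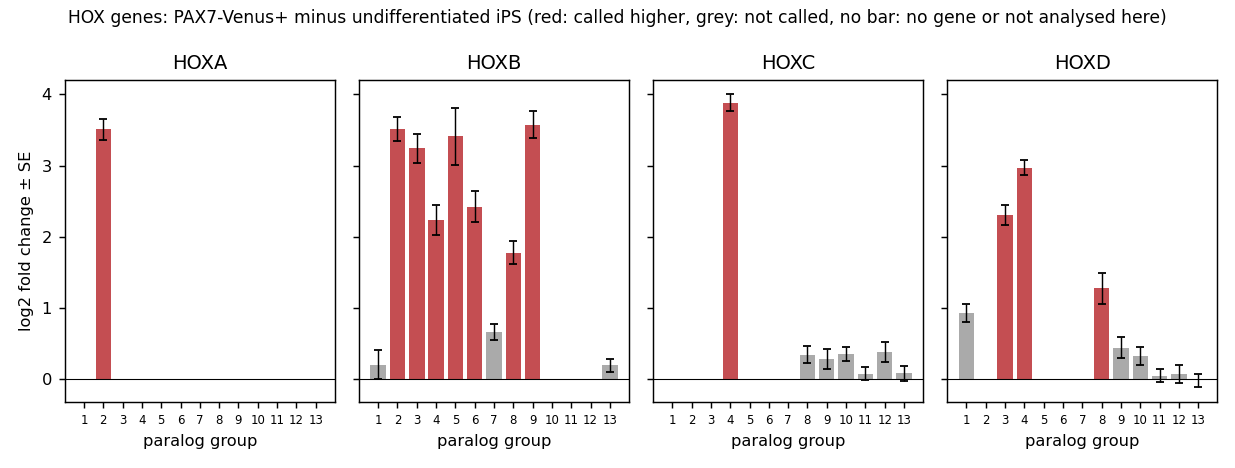
Log2 difference ± SE, PAX7-Venus+ minus undifferentiated iPS (y axis), of the 27 measured HOX genes by cluster (panels) and paralog group (x axis). Red bars are called higher, grey bars are not called, and a position with no bar has no gene or one not analysed here. The 12 called genes lie in paralog groups 2 to 9.

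Of the imprinted genes 11 of 19 were measured, of which 5 rose and 1 fell (median 0.38, camera in limma, adjusted p = 0.011, and adjusted p = 0.247 with an estimated correlation). With housekeeping centring the adjusted p was 0.0898. DLK1, which encodes a membrane protein of the Notch ligand family, rose by 4.53 (SE 0.36), PLAGL1 by 3.81 (SE 0.14) and PEG10 by 2.28 (SE 0.10). GRB10 fell by 1.01 (SE 0.10), just past the 2-fold minimum, and was not called with housekeeping centring (-0.61), a second quantile normalisation (-0.96), cyclic loess (-0.96), treat, or any of 4 single arrays left out.

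Markers of other cell types that the cultures could hold were examined in 9 lists, 0 of which were called in camera, at adjusted p-values from 0.140 for endoderm to 0.640 for neurons in limma. The smallest unadjusted p was 0.0810, and fry, which compares no list with other genes, called 3 of them, the endothelial, cardiac and endoderm lists. The endothelial list had a mean difference of -0.85, with 0 members higher and 2 lower, so its call does not show a rise. Some usual markers were not analysed here, such as TUBB3, NEFL and SNAP25 of neurons, PDGFRA and PDGFRB of fibroblasts, and CDH5 and TEK of endothelium. The uncalled lists therefore do not show that these cell types were absent. Of 16 neural progenitor genes 3 rose and 3 fell (median 0.21), among them the zinc finger genes ZIC1, higher by 2.74 (SE 0.20), and ZIC5 and ZIC2, which fell by 4.08 (SE 0.20) and 3.35 (SE 0.52). ZIC2 had signals of 8.17, 6.07 and 6.17 in the 3 Venus+ arrays and fell by 4.04 without replicate 1. PAX6, a neural factor, rose by 1.15 (SE 0.25, adjusted p = 0.0072 in limma), to a signal of 4.33 ± 0.49 (SD, n = 3). Without Venus+ replicate 3 its difference was 0.86, below the 2-fold minimum, and treat did not call it. Of 20 neuronal genes 10 were measured, with a median of 0.15. Of these 2 rose, STMN2 by 2.03 (SE 0.20) and DCX by 1.85 (SE 0.27), and 2 fell. Of the latter, SYT1 fell by 1.52 (SE 0.10). ZIC5, ZIC2 and SYT1 fell from undifferentiated signals of 9.72, 10.16 and 7.31, so these falls do not show that neural cells were absent.

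Of 12 neural crest and glial genes 1 rose and 3 fell (median -0.17, or 0.23 with housekeeping centring). SNAI2, which encodes a zinc finger repressor that is also used in mesoderm, rose by 4.30 (SE 0.13), while PMEL fell by 2.18 (SE 0.12) and ETS1 by 1.60 (SE 0.11). SOX10, the usual marker of this lineage, was at 5.41 ± 0.15 and 5.20 ± 0.10 (SD, n = 3 each), a difference of -0.21 (SE 0.11, adjusted p = 0.165 in limma) that turned to 0.19 with housekeeping centring. Of 14 skeletogenic genes 2 rose, SOX6 by 1.38 (SE 0.14) and PAX1 by 1.13 (SE 0.19), and 1 fell, CNMD by 3.77 (SE 0.12), with a median of 0.20. PAX1 differed by 0.90 without Venus+ replicate 1, and neither SOX6 nor PAX1 was called with treat. Of 14 fibroblast genes 3 rose and 1 fell (median 0.11), with LOX, a collagen cross-linking enzyme, higher by 4.47 (SE 0.41), PRRX1 by 1.12 (SE 0.12), and THY1 falling by 2.64 (SE 0.15). PMEL, CNMD and THY1 fell from undifferentiated signals of 8.11, 8.55 and 7.76, so these falls do not show that those cell types were absent. The mean signals of the skeletogenic and fibroblast lists were 4.71 and 5.09 in Venus+ replicate 1, against 4.45 and 4.80 in replicate 2 and 4.36 and 4.68 in replicate 3.

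Of 11 endothelial genes 0 rose and 2 fell (median 0.05), both of them VEGF receptor genes with a high undifferentiated signal, KDR by 5.35 (SE 0.20) and FLT1 by 4.68 (SE 0.11). Of 11 cardiac and smooth muscle genes 1 rose (median 0.05), the actin-binding protein gene TAGLN by 2.62 (SE 0.11). Of 11 endoderm genes 1 rose (median 0.31), the chemokine receptor gene CXCR4 by 2.96 (SE 0.23), which is also used by migrating muscle progenitors and counted in that list. Of 12 presomitic genes 0 rose and 1 fell (median 0.04), the Notch ligand gene DLL3 by 1.02 (SE 0.12), which was not called with housekeeping centring (-0.62), cyclic loess (-0.99), treat, or any of 3 single arrays left out.

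Immediate-early and stress genes, a list fixed because cell dissociation and sorting can raise them, were higher in the sorted cells. Of 19 measured members 12 rose and 2 fell, with a median of 2.22 (camera in limma, adjusted p = 1.9e-04, and adjusted p = 0.457 with an estimated correlation). FOS rose by 4.24 (SE 0.33) and by 2.21 in a second probe set, JUN by 3.92 (SE 0.22) and DUSP1 by 3.07 (SE 0.26), while FOSL1 fell by 1.33 (SE 0.15). With housekeeping centring 14 members were higher and 0 lower, and with treat 11 were higher and 0 lower. The mean signal of the list was 7.79, 7.29 and 7.89 in the 3 Venus+ arrays and 6.07 to 6.12 in the undifferentiated arrays. These are the same arrays on which every gene group above was compared.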

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

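The tests of the patterns described here were chosen only after the results were seen, except the counts over other splits of the arrays.

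Probe sets without a gene name entered the fit but no gene or gene list of the report. Of these, 2587 passed the same thresholds as higher in the Venus+ arrays and 1997 as lower, a signal not traced to genes here.

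There are 10 ways to split 6 arrays into 3 and 3, too few for a share under 0.05. The real split called 2910 genes and the highest of the others 0, so 1 of 10 splits gave as many. For the gene lists the real split called 13 and the highest of the others 13, and 3 of 10 splits gave as many, the other splits being mixtures that leave 2 arrays of 1 group against 1.

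Immediate-early and heat shock genes were higher in the sorted cells, with a list median of 2.22. A single deviating array is argued against, since the lowest median with 1 array left out was 2.08. Dissociation and sorting may account for the pattern, but the labels describe sorting of differentiated cultures alone, so sorting, the 3 weeks of differentiation, the reporter line and the origin of the arrays cannot be told apart. The members did not move as 1, since FOSL1 fell by 1.33 and MYC by 1.09. Neither fall was called with housekeeping centring (-0.93 and -0.69) or with treat. HSPA1A and HSPA1B, at 2.85 and 2.92, are near-identical copies whose probes can share signal, so they count as 1 observation at most.

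Replication genes were lower relative to mitotic genes in Venus+ cells. Of 16 replication genes 12 fell (median -1.84) and of 16 mitotic genes 3 fell (median -0.16), a difference of 1.67 between groups arranged by function after the values were seen, which is why a permutation test over genes that had been run was dropped and no p value is given. A smaller share of cycling cells was assumed to lower both groups alike. The difference exceeds the spread of the members (median absolute deviation at most 0.83), so the groups did not fall alike. That difference is the pattern itself, in groups arranged after the values were seen, and the assumption was not tested. A smaller share of cycling cells therefore stays open. A single deviating array is argued against by the lowest difference with 1 array left out, 1.59. A difference in origin between re-analysed and other arrays stays open, because 0 groups hold arrays of both origins and the 2 cannot be told apart. Housekeeping centring moved both medians alike, to -1.44 and 0.24, and a change in the cell cycle between pluripotent and myogenic cells, a difference the design names, may contribute but was not tested.

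Some stem cell and epithelial genes kept a clear signal in the sorted cells, LIN28B at 45.2% of its undifferentiated level, KRT18 at 33.8%, SALL4 at 13.9%, SOX2 at 11.6%, DPPA4 at 8.65% and CLDN6 at 8.42%. Residual undifferentiated cells would bring all their abundant transcripts, but ESRG, LIN28A and L1TD1 kept at most 1.17% with 2 SE added, below the lowest bound of the 6 genes, 7.29%. Residual cells are therefore argued against as the source of these 6 signals. Expression by the sorted cells themselves, and a background signal that differs between probe sets, may each contribute and were not tested.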

How the results depend on the processing

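No called list or called named gene changed sign in any setting run. Housekeeping centring turned the balance of rises and falls, the uncalled gene SOX10, and the medians of the uncalled FGF and IGF, dystrophin complex, and neural crest and glia lists. The medians of the dystrophin complex, neuron and endothelial lists, none of them called, also turned with dim genes or an array left out. PAX7 and the pluripotency, epithelial and myogenic commitment lists stayed on their side of the threshold in every setting run, and all 26 lists did with each array left out, with the replicate block, with the mean of a gene's probe sets and with dim genes left out, a filter chosen after the data were seen. With 1 array left out in turn, 1021 to 1064 genes were higher and 1819 to 1927 lower, and PAX7 ranged from 2.79 to 3.04. Other settings moved the counts further, to 1936 higher and 1080 lower with housekeeping centring (1540 and 1312 with HPRT1 left out of it), 2969 and 4271 with no fold minimum, 525 and 977 with treat, and 3686 and 3938 with every probe set counted on its own. The last 3 differ by construction, and the cause of the first was not tested beyond the shifts of 0.40 and 0.26. With an estimated correlation the medians stand and these lists lose their call: myogenic progenitor (1.26), sarcomere (1.12), synapse and coupling (0.85), matrix (2.85), cell cycle (-0.83), Notch (0.51), BMP and TGF-beta (1.21), HOX (0.66), imprinted (0.38) and stress (2.22). The synapse and coupling list lost its call at an estimated correlation of -0.049, below the preset 0.01. These losses can therefore not be put down to correlation between members alone. The estimated setting also tests each list on the 4 residual degrees of freedom of the fit. Housekeeping centring ended the calls of Notch (0.91) and imprinted genes (0.78), also with HPRT1 left out (0.77 and 0.64). The cause of this was not tested. Fry compares no list with other genes. Under it the CDK inhibitor and pocket protein (0.27), WNT (0.32), FGF and IGF (-0.16), endothelial (0.048), cardiac (0.051) and endoderm (0.31) lists also passed. These values are medians, and the mean of the endothelial list was -0.85, with 0 members higher and 2 lower. Of 87 named genes, 5 lost their call and 1 gained one with housekeeping centring, 3 lost it with cyclic loess, 1 with a second quantile normalisation, and 11 with treat (POU5F1, PAX6, DMD, GDF11, GRB10, DCX, SOX6, PAX1, PRRX1, DLL3 and FOSL1). The replicate numbers did not pair the samples, as same-numbered deviations correlated at -0.01, -0.05 and -0.03. With the number as a block 1045 genes were higher and 1865 lower, the same 2910 genes, because the fold minimum sets most calls. The olfactory receptor filter, the suffix filter and the actin and GAPDH comparison were not run. Background may compress folds of genes near the array median of 3.93, which was not tested.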

Other observations

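The gene sets in the next paragraphs were put together after their values were seen, so they describe and do not test. Of 16 measured genes linked to the switch between epithelial and mesenchymal states 7 rose, 3 fell and 6 were not called. The 16 include the antisense RNA genes ZEB1-AS1 (0.06, not called) and ZEB2-AS1 (4.15, called higher), so ZEB2 and its antisense gene are counted separately among the rises. The repressor genes ZEB1, ZEB2 and SNAI1 rose by 4.67 (SE 0.20), 4.13 (SE 0.16) and 1.91 (SE 0.12), beside SNAI2 in the report, while ESRP2 and GRHL2, which maintain epithelial splicing and junctions, fell by 2.54 (SE 0.11) and 3.64 (SE 0.11). Other genes of the epithelial side were not called, GRHL1 at 0.00, GRHL3 at -0.21, OVOL1 at -0.59 and OVOL2 at -0.99. TWIST1 rose by 1.03 and was below 2-fold without Venus+ replicate 1 (0.85) or undifferentiated replicate 3 (0.91), and TWIST2 was at -0.03. All 5 genes of the MIR302 and MIR367 cluster, a microRNA locus active in pluripotent cells, fell. MIR302A fell by 5.92 (SE 0.09) and MIR367 by 5.39 (SE 0.13). The Venus+ signals of these 2, 2.43 and 2.04, were below 3.93 and not shown to be above background, so the exact differences are uncertain.

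Of 8 genes of homeobox cofactors and EBF factors 4 rose and 4 were not called. MEIS1 rose by 5.03 (SE 0.09) and MEIS2 by 4.11 (SE 0.20), whereas PBX3 (0.13) and PKNOX1 (-0.23) were not called. EBF3, a transcription factor gene of somitic and neural tissue, rose by 4.31 (SE 0.10), while EBF1 (0.90, SE 0.38) and EBF2, 2.83-fold higher with signals of 3.49 ± 0.05 and 5.00 ± 1.60 (SD, n = 3 each), were not called. Of the measured HOX genes, 12 of 18 in paralog groups 1 to 9 were called higher and 0 of 9 in groups 10 to 13, where the largest difference was 0.39 for HOXC12 and HOXC10 (0.36, adjusted p = 0.0227 in limma) passed the p threshold alone. This split was chosen after the values were seen, so a Fisher's exact test of it that had been run is not used here.

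Genes of the FGF family went both ways. FGF7, FGF9 and FGF10 rose by 3.84, 5.08 and 3.11, FGF2 fell by 1.91 and FGF19 fell by 1.91, and others such as FGF4 (-0.16), FGF8 (0.35) and FGF13 (-0.23) were not called. Of 5 genes that FGF signalling induces, 4 fell and SPRY2 (-0.88) was not called. DUSP6 fell by 4.17, SPRY4 fell by 3.52, ETV4 fell by 4.82 and ETV5 fell by 2.75. Of 9 metallothionein genes, which encode metal-binding proteins, 4 fell and 0 rose, MT1G by 4.76 (SE 0.14) and MT1X by 3.03 (SE 0.12), and MT1 genes are similar copies whose probes can share signal. Of 10 proteoglycan genes 6 rose, and the Venus+ arrays differed widely in PRG4 at 7.93 ± 1.93, OGN at 7.95 ± 1.46 and FMOD at 7.81 ± 1.15 (SD, n = 3 each).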
